A study of Bos taurus with 21 samples.

How the data were processed

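Liver RNA of 21 steers (Bos taurus) was profiled on single-colour whole-transcript arrays, with 1 array per steer. The animals grazed tall fescue that carried a fungal endophyte and received vitamin-mineral mixes with 1 of 3 forms of selenium. Per the labels, the mix held sodium selenite in the ISe group (n = 6), the commercial selenium product SEL-PLEX in the OSe group (n = 8) and both in a 1:1 blend in the MIX group (n = 7). Liver was taken from the right lobe directly after death, frozen in liquid nitrogen and extracted with TRIzol, and the RNA was fragmented and labelled with biotin, per the labels' protocols. The sample titles call the samples biological replicates, and each was treated as 1 animal.

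The deposited table held 1 value per probe set and array, on what the range of 1.63 to 14.4 shows to be a log scale, taken here as log2. Neither the log base nor the method of normalisation is given in the sources used here, and every fold change below assumes base 2. The submitters' processing notes name GCOS 1.2 and Partek, without saying what each was used for. Array medians lay between 6.43 and 6.50, and arrays differed at equal rank by an SD of at most 0.0768, so the authors' values were already scaled between arrays and were used as deposited. Correlations between pairs of arrays over all probe sets ran from 0.981 to 0.989. No detection calls or background values were used here, so a dim probe set could not be told from one without signal, and the number of arrays limits the precision. All 26773 probe sets were tested. Control probe sets were to be left out, but they could not be told apart here, so probe sets without a name stayed in the tests. As an alternative added after seeing the data, the tests were run on the probe sets with 1 gene symbol only.

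Gene names came from the platform annotation, in which 18457 probe sets had 1 symbol, 688 had several and 7628 were not listed. Of these names, 17996 matched a gene identifier in the current gene table of the assembly ARS-UCD2.0, and 0 symbols changed by the match. No gene was named from a probe set with several symbols, for which reason GLUL is not reported here. The named genes stood for 18010 measured genes, of which 401 had more than 1 probe set and were represented by the brightest. A group of 297 probe sets fell into 114 sets with identical values on every array. The genome build of the array is not given in the sources used here, and no coordinates are printed.

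Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per group and all 21 arrays sharing 1 estimate of the spread. The fit had 18 residual and 3.76 prior degrees of freedom. The tests were a moderated F test over the 3 groups, the 3 pairwise differences, and the difference of MIX from the mean of ISe and OSe. The p-values were adjusted by the method of Benjamini and Hochberg over all probe sets of a test, with a threshold of 0.05, and 95% confidence intervals came from the same fit. A set of 42 gene lists, 14 of them cell type markers, held 1091 symbols, of which 940 were measured. Lists were tested with camera at a preset correlation between genes of 0.01, again with a correlation estimated for each list, and with fry, which asks whether the genes of a list move on balance one way, or in its mixed form whether they change in either direction. Marker lists were also averaged per steer and compared by exact two-sided permutation tests, adjusted over 42 tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

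The groups, the tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. By that rule the text names, for each pair of groups, up to 10 of the strongest increases and up to 10 of the strongest decreases past the threshold, or the 10 smallest p-values where fewer than 10 passed. For each called list it names up to 4 members, and it always names 14 genes of selenium use, nitrogen and growth metabolism. Genes outside the rule are said to have been chosen after their values were seen. The alternatives were quantile normalisation, centring of each array on its median, leaving out the 40% of probe sets with the lowest mean, other variance models, array weights, a residual principal component as covariate, the replicate number as a block, fits of only 2 groups, the mean over probe sets of a gene, a threshold of 0.10, and leaving out each steer in turn.

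The procedure was tested on simulated data with the real spread of the 26773 probe sets and 50 changed probe sets per size. For OSe against ISe it recovered 66% of changes of 0.5 on the log2 scale and 96% of changes of 1. For MIX against ISe the shares were 74% and 94%, and for OSe against MIX 62% and 92%. The false calls numbered 9, 11 and 16 in the same order. All calls in these simulations numbered 188, 194 and 191, against 22, 1 and 1 in the real data. The adjustment is stricter where fewer probe sets pass, so these shares are likely to overstate what the real comparisons could recover. Few real calls therefore do not show that large changes were absent. A list of 66 genes shifted by 0.3 was called in every pair, both with the preset and with the estimated correlation, and 0 other lists were called. The simulated noise was independent between genes. The simulation therefore cannot show how often lists are falsely called when their genes vary together.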

Results

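Hepatic gene expression was measured in 21 steers on fescue pasture. The steers received selenium as sodium selenite (ISe, n = 6), as SEL-PLEX, a selenium-enriched yeast (OSe, n = 8), or as a blend of equal parts of these (MIX, n = 7). The comparisons ask whether the form of selenium in a vitamin-mineral mix changes gene expression in the liver. Values are log2 array signals over 26773 probe sets, with array medians of 6.43 to 6.50. The median difference over all probe sets was 0.0047 for OSe minus ISe and 0.0053 for MIX minus ISe. The first principal component held 9.77% of the variance. Its means were 16.0 ± 8.20 in ISe, -5.03 ± 9.82 in MIX and -7.62 ± 5.16 in OSe (SD).

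Steers given SEL-PLEX had lower hepatic expression of 19 probe sets than steers given selenite, among them those of PDK4, DUSP1, ALAS1, TP53INP1, DDIT4 and TXNIP. PDK4, the kinase that switches off pyruvate dehydrogenase, averaged 10.40 ± 0.76 in ISe (SD, n = 6) and 8.87 ± 0.34 in OSe (SD, n = 8). It fell by 1.54 ± 0.26 (SE) on the log2 scale, a 2.90-fold difference (limma, adjusted p = 0.0268). DUSP1, a phosphatase that ends MAP kinase signalling, fell 2.15-fold, and ALAS1, the first enzyme of haem synthesis, fell by 1.08 ± 0.21 (adjusted p = 0.0457 and 0.0492). TP53INP1, a p53-induced stress protein, fell by 1.01 ± 0.17 and DDIT4, an inhibitor of mTORC1, fell by 0.93 ± 0.15. TXNIP, the inhibitor of thioredoxin, fell by 0.66 ± 0.11 (adjusted p = 0.0268 for each of these 3 genes).

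Other decreases past the threshold were found for PPTC7, a mitochondrial phosphatase (-0.99), and the protocadherin PCDH19 (-0.99). LURAP1L (-0.94), MAEL (-0.94), which was dim at percentile 29.9 of mean signal, and NOPCHAP1 (-0.82) completed the 10 strongest decreases. The potassium channel KCNK5 (-0.77), JCAD (-0.68) and AUTS2 (-0.68) fell too. Among genes with 1 established name, they had 3 of the 10 smallest p-values of the test over the 3 groups. The remaining decreases with a single symbol were named after their values were seen. They were the cytokine receptor IL7R (-0.70), TNFAIP3 (-0.54), which restrains NF-kappa B signalling, and TOB1 (-0.42), an antiproliferative protein. Increases were fewer, 3 in all. ZC3H12D, an RNA-binding protein of immune cells, rose by 0.43 ± 0.08 (adjusted p = 0.0298). The olfactory receptor gene OR8G3E (0.52) and C3H1orf146 (0.38) also rose, but both were dim, at percentiles 9.35 and 7.69 of mean signal.

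Of 26773 probe sets, 22 passed an adjusted p of 0.05 in OSe against ISe, 19 of them lower in OSe. An unadjusted p under 0.05 was seen for 2662, against a mean of 1338.65 by chance. Probe sets are not independent, and the spread of the chance count around that mean was not measured. PDK4 was lower in 7 of 8 OSe steers than in any ISe steer. The number of calls depended on single animals. It was 0 without OSe steer 2, 3 or 4 or ISe steer 4, 5 or 6. It was 5 without OSe steer 8, 10 without OSe steer 7, and 14 without MIX steer 4 or OSe steer 5. It rose to 39 without OSe steer 1, 41 without ISe steer 1 and 44 without ISe steer 2. An unmoderated linear model called 0, with 2601 at an unadjusted p under 0.05. A fit of only these 2 groups called 1, and quantile normalisation called 14, of which 13 were among the 22. Leaving out dim probe sets, array weights, a residual principal component and testing only singly named probe sets gave 44, 44, 38 and 45.

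**Figure D1:**
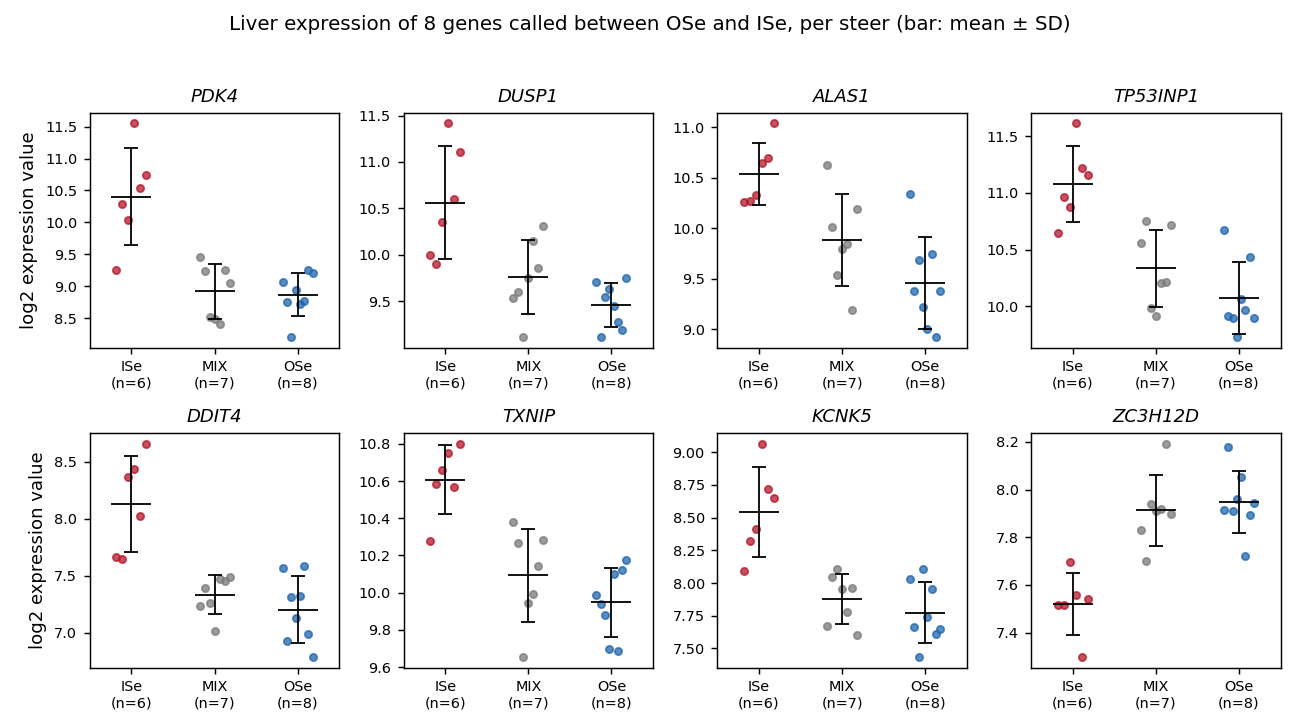
Log2 array signal (vertical axis) of 8 genes in each steer of the ISe (n = 6), MIX (n = 7) and OSe (n = 8) groups, 1 point per steer, with the group mean and SD as bars. PDK4 averaged 10.40 in ISe, 8.92 in MIX and 8.87 in OSe, and the 8 genes passed an adjusted p of 0.05 between OSe and ISe.

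Genes of cholesterol synthesis and uptake were lower in OSe than in ISe in 17 of 17 measured members, with a median difference of -0.37 (camera, adjusted p = 4.24e-12; adjusted p = 0.171 with an estimated correlation). SQLE (-0.58), MVD (-0.53), LSS (-0.51) and NSDHL (-0.38), enzymes of sterol synthesis, were among 7 members lower when adjusted over the list alone. None of the 17 passed over all genes. Fatty acid and triglyceride synthesis was lower as well, with a median of -0.07 over 25 genes (adjusted p = 0.00518; adjusted p = 0.471 with an estimated correlation). Its 5 members lower when adjusted over the list alone, against none over all genes, included the lipogenic regulator THRSP (-0.91) and fatty acid synthase FASN (-0.61). ACSS2 (-0.65), which makes acetyl-CoA from acetate, was another. Fatty acid oxidation and ketogenesis had a median of -0.12 with 20 of 24 members below 0 (adjusted p = 0.00185; adjusted p = 0.465 with an estimated correlation). CPT1A (-0.27), the entry enzyme of mitochondrial oxidation, and ANGPTL4 (-0.72, and -0.47 without ISe steer 4) belong to it. None of its members passed over all genes or adjusted over the list alone.

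The lists of the urea cycle, amino acid catabolism and one-carbon metabolism were called lower in OSe too, at the preset correlation only. The urea cycle list had a median of -0.24 with 9 of 10 members below 0 (camera, adjusted p = 3.12e-05; adjusted p = 0.171 with an estimated correlation). NAGS (-0.50), SLC25A15 (-0.46), ARG1 (-0.42) and ARG2 (-0.31) were lower when adjusted over the list alone and none over all genes. CPS1, the first enzyme of the cycle, differed by -0.08 ± 0.06 (adjusted p = 0.665), and by -0.05 without ISe steer 5. Amino acid catabolism had a median of -0.13 with 25 of 32 members below 0 (adjusted p = 6.6e-06; adjusted p = 0.383 with an estimated correlation). HAL (-1.25), which breaks down histidine, and OAT (-0.50) were among 5 members lower when adjusted over the list alone, none over all genes. Methionine and one-carbon metabolism had a median of -0.07 (adjusted p = 0.0194; adjusted p = 0.465 with an estimated correlation). GLDC (-0.55), of glycine cleavage, was its 1 member lower when adjusted over the list alone, with none over all genes.

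Cytochrome P450 and drug metabolism had a median of -0.12 in OSe minus ISe with 24 of 32 members below 0 (camera, adjusted p = 9.92e-05; adjusted p = 0.225 with an estimated correlation). CYP1A1 (-0.98), CYP4V2 (-0.46), UGT2A1 (-0.44) and SULT1A1 (-0.25) were among 5 members lower when adjusted over the list alone, none over all genes. The 2 lists of liver zone markers were called lower as well. All 12 measured periportal markers were below 0, with a median of -0.24 (adjusted p = 3.26e-06; adjusted p = 0.0704 with an estimated correlation). Glutaminase GLS2 (-1.25) and HAL were lower when adjusted over the list alone and no member over all genes. The periportal list shares 4 genes with the urea cycle list and 2 with amino acid catabolism, and the pericentral list shares 2 with the cytochrome P450 list and 1 with amino acid catabolism. Pericentral markers had a median of -0.15 with 9 of 12 members below 0 (adjusted p = 0.0266; adjusted p = 0.171 with an estimated correlation). OAT, TBX3 (-0.36), RNF43 (-0.34) and CYP1A2 (-0.23) were lower when adjusted over the list alone, none over all genes. Averaged per steer, periportal markers stood at 10.34 ± 0.15 in OSe and 10.72 ± 0.14 in ISe (SD; exact permutation p = 0.00167, adjusted p = 0.0699). Hepatocyte identity markers stood at 11.97 ± 0.05 and 12.01 ± 0.04 (exact permutation p = 0.164, adjusted p = 0.644).

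The lists of early response genes and clock genes were called lower in OSe at the preset correlation only. Immediate early genes had a median of -0.18 with 17 of 26 members below 0 (camera, adjusted p = 0.000545; adjusted p = 0.383 with an estimated correlation). Of these, 7 were lower when adjusted over the list alone against 1, DUSP1, over all genes. Clock genes had a median of -0.10 (adjusted p = 0.00356; adjusted p = 0.171 with an estimated correlation). NOCT (-0.96), PER1 (-0.73) and CRY2 (-0.33) were lower when adjusted over the list alone, none over all genes. Cytosolic ribosomal protein genes had a median of -0.05 with 29 of 37 members below 0 (adjusted p = 0.000948; adjusted p = 0.57 with an estimated correlation). Stellate cell and fibroblast markers, among them PDGFRA (-0.27) and DCN (-0.24), had a median of -0.07 (adjusted p = 0.0141; adjusted p = 0.585 with an estimated correlation). Neither list had a member past over all genes or adjusted over the list alone.

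Proteasome and unfolded protein response genes were called higher in OSe at the preset correlation only, while heat shock proteins were not called (camera, adjusted p = 0.678). Proteasome genes had a median of 0.13 with 28 of 30 members above 0, led by PSMC4 at 0.27 (camera, adjusted p = 1.11e-06; adjusted p = 0.471 with an estimated correlation). None passed over all genes or adjusted over the list alone. The unfolded protein response list had a median of 0.16 with 23 of 27 members above 0 (adjusted p = 0.000505; adjusted p = 0.564 with an estimated correlation). Asparagine synthetase ASNS (0.81) was its 1 member higher when adjusted over the list alone, with none over all genes, and the chaperones CALR and CANX stood at 0.31 and 0.21. Kupffer cell and macrophage markers had a median of 0.11 (adjusted p = 0.032; adjusted p = 0.672 with an estimated correlation). VSIG4 (0.30) and TYROBP (0.20) belong to this list, which had no member past either adjustment.

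Camera called 16 of 42 lists between OSe and ISe, 13 lower and 3 higher in OSe. With estimated correlations 0 calls held in any pair of groups, with 6, 3 and 1 lists at an unadjusted p under 0.05 for OSe minus ISe, MIX minus ISe and OSe minus MIX, where fry called 1, 0 and 0. The mixed test of fry, which asks for change in either direction and does not compare a list with other genes, called 19, 19 and 0. Leaving out 1 steer ended 6 of the calls between OSe and ISe. Stellate cells and fibroblasts lost its call without ISe steer 2 (adjusted p = 0.816), fatty acid and triglyceride synthesis without ISe steer 4 (0.0559) and cytosolic ribosomal proteins without OSe steer 7 (0.0687). Pericentral hepatocyte zone was lost without ISe steer 4 or 5 or OSe steer 3 (0.0563, 0.0722 and 0.0594). Methionine, cysteine and one-carbon metabolism was lost without ISe steer 4, 5 or 6 or OSe steer 5 (0.0521 to 0.0754). Kupffer cells and macrophages was lost without ISe steer 4 or 5 or OSe steer 1, 3, 5 or 8 (0.0785 to 0.199).

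**Figure D2:**
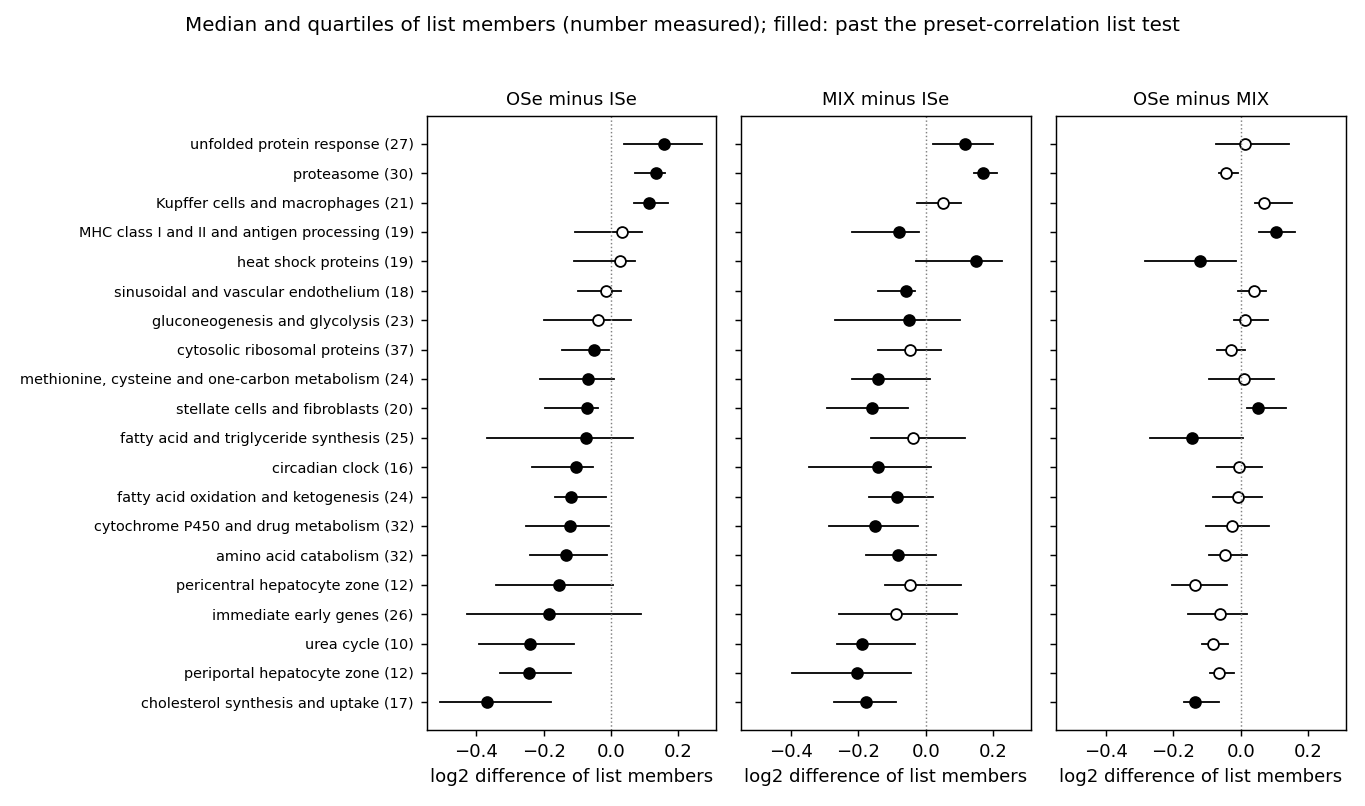
Median log2 difference with quartiles (horizontal axis) of the 20 gene lists called in any pair of groups, in panels for OSe minus ISe, MIX minus ISe and OSe minus MIX, with filled symbols for calls by camera at the preset correlation. Cholesterol synthesis and uptake had a median of -0.37 for OSe minus ISe and -0.18 for MIX minus ISe.

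Set against selenite, the blend gave differences of the same sign as SEL-PLEX in PDK4, DDIT4 and the other called genes. Shared signs are likely without any effect, since both differences use the same 6 ISe steers (21.3 of 22 on average in simulations). A single probe set passed the test of MIX against ISe. LOC619000, named after its values were seen, fell by 0.65 ± 0.10 in MIX, a 1.57-fold difference (limma, adjusted p = 0.0241). It was dim, at percentile 27.2 of mean signal. PDK4 differed by -1.49, DDIT4 by -0.80, AUTS2 by -0.72, KCNK5 by -0.67 and the amino acid transporter SLC43A2 by -0.44. ZNF74 differed by 0.69, FAM174B by 0.64, MACIR by 0.62, the mitochondrial NAD kinase NADK2 by 0.61 and ZC3H12D by 0.39. Each of these 10 had an adjusted p of 0.111. An unadjusted p under 0.05 was seen for 2790 probe sets. An unmoderated linear model called 0, with 2763 at an unadjusted p under 0.05, and array weights gave 5. With dim probe sets left out, 0 passed. Without MIX steer 4, 6 or 7 or ISe steer 3, 4, 5 or 6 the count was 0. It was 2 without OSe steer 1 or ISe steer 2, 3 without MIX steer 2 or ISe steer 1, and 12 without MIX steer 1.

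Proteasome genes were higher in the blend than in ISe, with 29 of 30 members above 0 and a median of 0.17 (camera, adjusted p = 1.36e-10; adjusted p = 0.451 with an estimated correlation). PSMD14 stood at 0.30 and PSMA7 at 0.23, and none passed over all genes or adjusted over the list alone. Stellate cell and fibroblast markers were lower, with a median of -0.16 (adjusted p = 1.42e-05; adjusted p = 0.451 with an estimated correlation). Without ISe steer 2 the list of stellate cells and fibroblasts had an adjusted p of 0.0209, and the difference between the group averages of its markers went from -0.19 to -0.08. RGS5 (-0.64), LRAT (-0.51), COL6A3 (-0.33) and PDGFRA (-0.33) were lower when adjusted over the list alone, none over all genes. All 17 cholesterol genes lay below 0, with a median of -0.18 (adjusted p = 0.000106; adjusted p = 0.548 with an estimated correlation). INSIG1 (-0.87) and FDFT1 (-0.67) led, and none passed either adjustment. Periportal markers had a median of -0.20 (adjusted p = 0.00115; adjusted p = 0.36 with an estimated correlation). GLS2 (-1.23), HAL (-1.22) and PCK1 (-0.58) were lower when adjusted over the list alone, none over all genes. Cytochrome P450 genes had a median of -0.15 and no member past either adjustment (adjusted p = 0.00115; adjusted p = 0.451 with an estimated correlation). Amino acid catabolism had a median of -0.08 (adjusted p = 0.0047; adjusted p = 0.631 with an estimated correlation). HAL, OAT (-0.43) and FAH (-0.29), of tyrosine breakdown, were its 3 members lower when adjusted over the list alone, none over all genes. Clock genes had a median of -0.14 (adjusted p = 0.0068; adjusted p = 0.36 with an estimated correlation). NOCT (-0.89), NPAS2 (-0.55), PER1 (-0.47) and CRY2 (-0.31) were lower when adjusted over the list alone, none over all genes.

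Glucose metabolism genes went both ways in the blend. The gluconeogenesis and glycolysis list was called lower in MIX than in ISe with a median of -0.05 (camera, adjusted p = 0.0206; adjusted p = 0.451 with an estimated correlation). PDK4, G6PC1 (-0.67) and PCK1 (-0.58), enzymes of glucose sparing and output, and the glycolytic PKLR (-0.35) were among 6 members lower when adjusted over the list alone. The glycolytic ALDOA (0.30) and ENO1 (0.24), chosen after their values were seen, were higher by the same adjustment, and none passed over all genes. In OSe against ISe this list was not called (adjusted p = 0.0782; adjusted p = 0.496 with an estimated correlation). Fatty acid oxidation and ketogenesis was lower in MIX (median -0.09, adjusted p = 0.0173; adjusted p = 0.609 with an estimated correlation). So was the urea cycle (-0.19, adjusted p = 0.0206; adjusted p = 0.548 with an estimated correlation). Methionine, cysteine and one-carbon metabolism had a median of -0.14 (adjusted p = 0.0415; adjusted p = 0.606 with an estimated correlation), with BHMT at -0.47. Unfolded protein response was higher (median 0.12, adjusted p = 0.0173; adjusted p = 0.641 with an estimated correlation), with XBP1 at 0.35. Heat shock proteins were higher too (0.15, adjusted p = 0.0322; adjusted p = 0.641 with an estimated correlation), with HSPH1 at 0.43.

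The lists of endothelial and antigen presentation genes were called lower in the blend at the preset correlation only. Sinusoidal and vascular endothelium had a median of -0.06 (camera, adjusted p = 0.0322; adjusted p = 0.548 with an estimated correlation), with OIT3 (-0.31) lower when adjusted over the list alone and none over all genes. MHC class I and II and antigen processing had a median of -0.08 (adjusted p = 0.0337; adjusted p = 0.641 with an estimated correlation), with BOLA-DQA1 at -1.18 ± 0.47. That value was -0.72 without MIX steer 7, and another, dim probe set of BOLA-DQA1 differed the other way, by 0.96. In the fatty acid oxidation, urea cycle, unfolded protein response, heat shock and MHC lists no member passed over all genes or adjusted over the list alone. In the methionine list 1 member, GNMT (0.63), was higher when adjusted over the list alone, against the direction of the list, and none passed over all genes. GNMT was chosen after its value was seen.

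Of the 15 lists called between MIX and ISe, 7 stayed called with each steer left out in turn. Fatty acid oxidation and ketogenesis was lost without ISe steer 4 (adjusted p = 0.0787) or MIX steer 5 (0.0512). Gluconeogenesis and glycolysis was lost without ISe steer 3 (0.0535) or 6 (0.0709) or MIX steer 2 (0.0859), and urea cycle without ISe steer 5 (0.134) or 6 (0.0709) or MIX steer 5 (0.0512). Unfolded protein response was lost without ISe steer 3 (0.208) or 6 (0.181) or MIX steer 3 (0.0659) or 5 (0.0886). For heat shock proteins it was ISe steer 3 or 6 or MIX steer 4, 5 or 6 (0.0549 to 0.189). For sinusoidal and vascular endothelium it was ISe steer 1, 2 or 6 or MIX steer 2, 3 or 6 (0.0602 to 0.118). For MHC class I and II and antigen processing it was ISe steer 1, 2 or 3 or MIX steer 2, 5 or 6 (0.0603 to 0.173). For methionine, cysteine and one-carbon metabolism it was ISe steer 3, 4, 5 or 6 or MIX steer 3, 5 or 6 (0.0624 to 0.129).

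SEL-PLEX and the blend were set side by side in their differences from selenite. All 22 probe sets called in OSe had the same sign in MIX, and the 19 decreases had a median of -0.65 in MIX and -0.82 in OSe. Both differences use the same 6 ISe steers. In 100 simulations without any effect, 18 to 22 of the 22 smallest p-values shared their sign, with a mean of 21.3. Between 1 and 22 of them also reached an unadjusted p under 0.05 in MIX, where 22 did in the data. The limma calls of the 2 comparisons shared 0 probe sets, from 2662 and 2790 at an unadjusted p under 0.05, and an unmoderated linear model called 0 in each. Simulations without effect gave 0.01 shared calls, and independent lists would share 0.00071 in the same direction. Across probe sets, which are not independent replicates, the differences correlated at 0.687. The value was 0.546 (0.340 to 0.736) without effect and 0.261 (0.185 to 0.295) with the ISe steers split 3 and 3. Their covariance was 0.0192 against 0.0104 (0.00474 to 0.0141), an excess of 0.00878. The same sign was seen in 72.3% of probe sets against 68.4% (59.0 to 76.2%) without effect, so it lay within that range.

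Between SEL-PLEX and the blend, LRAT, the enzyme that stores vitamin A as retinyl esters, was the 1 gene past the threshold. It rose by 0.70 ± 0.11 in OSe against MIX, a 1.63-fold difference (limma, adjusted p = 0.0354), with all 8 OSe steers above all 7 MIX steers. It averaged 7.55 ± 0.17 in ISe, 7.04 ± 0.31 in MIX and 7.74 ± 0.13 in OSe (SD). Unnamed probe sets left aside, the next genes did not pass, with adjusted p from 0.285 to 0.344. They were PIK3C2A (-0.30), JPH4 (0.30), TSC22D1 (-0.46), the neutrophil protein S100A12 (-0.44) and tyrosine aminotransferase TAT (-0.53). PLOD2 (-0.34), TDG (-0.21), LRRTM2 (-0.26) and FAM174B (-0.48) followed. In MIX, LRAT and LOC619000 departed from the midpoint of ISe and OSe, by -0.61 ± 0.10 and -0.54 ± 0.08 (adjusted p = 0.0314 and 0.0257). An unadjusted p under 0.05 was seen for 1571 probe sets in OSe against MIX and 2042 in the midpoint test. An unmoderated linear model called 0 in both tests, with 1564 and 2031 at an unadjusted p under 0.05. A fit of only OSe and MIX called 0. So did the fit without MIX steer 1, 2, 6 or 7, OSe steer 3, 4, 5, 6, 7 or 8 or ISe steer 2, 4 or 6. Without OSe steer 1 LRAT missed the threshold (limma, adjusted p = 0.0546) and the 1 call was TAT, lower in OSe by 0.64 (adjusted p = 0.0119). The midpoint test gave 4 without MIX steer 1 or 2, and 1 with dim probe sets left out. It also gave 1 without MIX steer 4 or OSe steer 1, 3, 5, 6, 7 or 8, and 0 without MIX steer 6 or 7, OSe steer 4 or ISe steer 2, 4, 5 or 6.

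The lists of heat shock proteins and lipid synthesis were called lower in OSe than in MIX at the preset correlation only. Of 100 splits of these steers, the real one included, 65 gave at least as many called lists as the real 5. Heat shock proteins had a median of -0.12 (camera, adjusted p = 0.00139; adjusted p = 0.754 with an estimated correlation). DNAJB4 (-0.43), HSPA4L (-0.39) and BAG3 (-0.38) were lower when adjusted over the list alone, none over all genes. Fatty acid and triglyceride synthesis had a median of -0.14 (adjusted p = 0.00272; adjusted p = 0.754 with an estimated correlation), led by ACSS2 (-0.62), THRSP (-0.56) and the desaturase SCD (-0.53). Cholesterol synthesis and uptake had a median of -0.14 with 16 of 17 members below 0 (adjusted p = 0.00272; adjusted p = 0.754 with an estimated correlation), LSS at -0.37. MHC class I and II and antigen processing was higher, with a median of 0.10 and TAPBP at 0.17 (adjusted p = 0.009; adjusted p = 0.754 with an estimated correlation). In the lipid and MHC lists no member passed over all genes or adjusted over the list alone. Stellate cell and fibroblast markers were higher, with a median of 0.05 (adjusted p = 0.0436; adjusted p = 0.754 with an estimated correlation). Of these, 2 were higher when adjusted over the list alone and 1, LRAT, over all genes.

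The 5 list calls between OSe and MIX became 8 without MIX steer 1 or OSe steer 2 or 4, 3 without MIX steer 7 or OSe steer 8 and 2 without OSe steer 5. Cholesterol synthesis and uptake was lost without MIX steer 4 or 7 or OSe steer 5 (adjusted p 0.0525 to 0.107), and fatty acid and triglyceride synthesis without MIX steer 7 (0.066). MHC class I and II and antigen processing was lost without MIX steer 2 or 5 or OSe steer 5 or 8 (0.0502 to 0.135). Stellate cells and fibroblasts was lost without MIX steer 3, 5 or 7 or OSe steer 3, 5, 7 or 8 (0.0547 to 0.189).

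Selenoprotein transcripts, the products most directly tied to selenium supply, did not pass the test in any pair of groups. For OSe minus ISe, the glutathione peroxidases GPX1, GPX3 and GPX4 differed by -0.14 (95% interval -0.31 to 0.04), 0.21 (-0.63 to 1.06) and 0.11 (-0.14 to 0.35). The plasma selenium carrier SELENOP differed by -0.06 (-0.18 to 0.06) and SELENOW by -0.13 (-0.30 to 0.04). Thioredoxin reductase TXNRD1 differed by 0.17 (-0.01 to 0.35), the thyroid hormone deiodinase DIO1 by 0.65 (-0.05 to 1.35) and MSRB1 by -0.03 (-0.22 to 0.16). SEPHS2, which makes the selenium donor of selenocysteine, differed by 0.04 (-0.14 to 0.21) and SCLY, which recycles selenocysteine, by -0.10 (-0.25 to 0.04). For MIX minus ISe, GPX4 differed by 0.29 ± 0.12 and TXNRD1 by 0.20 ± 0.09 (adjusted p = 0.418 and 0.455). GPX3 spread widely, with SDs of 0.68 in ISe, 0.28 in MIX and 1.16 in OSe. Its difference between OSe and ISe was -0.15 without OSe steer 3, 0.49 without ISe steer 4, 0.14 without ISe steer 6, 0.36 without OSe steer 2 and 0.35 without OSe steer 4. Small differences between OSe and ISe also moved with single steers. SELENOW was at -0.08 without ISe steer 6, SCLY at -0.05 without ISe steer 3, and GPX4 at 0.05 and 0.06 without ISe steer 2 and OSe steer 2. MSRB1 ranged over -0.07 to 0.02 and SEPHS2 over 0.0018 to 0.078 with 1 steer left out. The 25 measured selenoprotein genes were not called as a list (camera, adjusted p = 0.394 for OSe minus ISe, 0.438 for MIX minus ISe and 0.84 for OSe minus MIX). Limma called 0 members over all genes or adjusted over the list alone. The mixed test of fry, for change in either direction, gave adjusted p = 0.31, 0.0222 and 0.912 in the same order. That test called 19 of 42 lists for MIX minus ISe, so its result there is not particular to selenoproteins. An unadjusted p under 0.05 was seen for 2, 7 and 0 members in the same order, and for 2, 8 and 0 in an unmoderated linear model.

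Of 16 genes of selenium use and selenoprotein synthesis, SELENBP1, PSTK and TPMT were chosen after their values were seen. SELENBP1, a selenium-binding methanethiol oxidase, differed by -0.61 ± 0.15 in OSe and -0.65 ± 0.15 in MIX against ISe (limma, adjusted p = 0.123 and 0.129). PSTK, a kinase of selenocysteine synthesis, differed by -0.39 ± 0.12 in OSe (adjusted p = 0.225), and TPMT, a methyltransferase, by 0.32 in MIX. These differences passed when adjusted over the list alone, and no member passed over all genes. The list was not called by camera (adjusted p = 0.287 for OSe minus ISe and 0.694 for MIX minus ISe). The mixed test of fry gave adjusted p = 0.0249 and 0.0238, but it called 19 of 42 lists in each of these comparisons. Its result is therefore not particular to genes of selenium use.

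**Figure D3:**
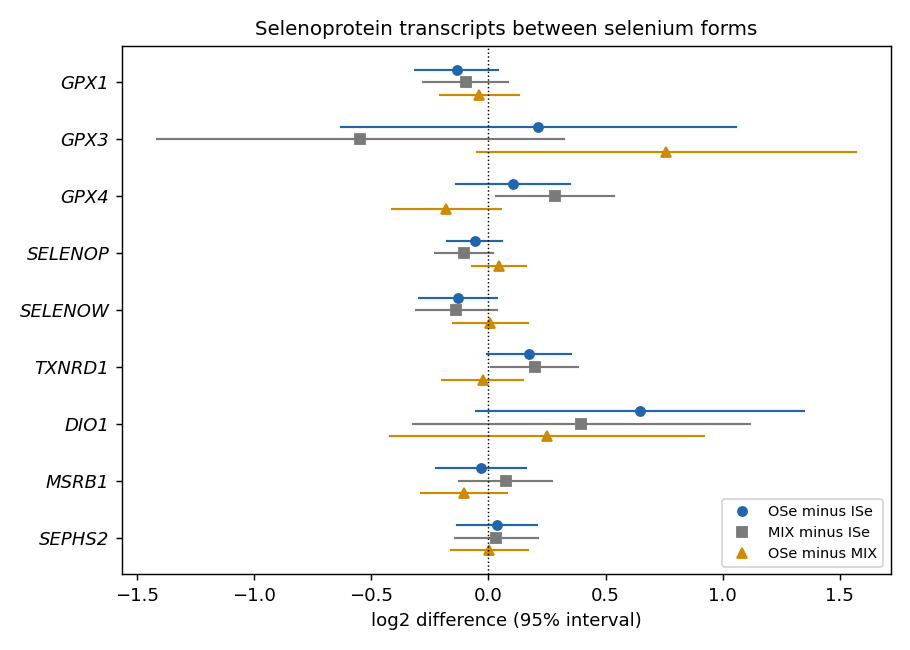
Log2 difference with its 95% interval (horizontal axis) of 9 selenoprotein transcripts for OSe minus ISe, MIX minus ISe and OSe minus MIX (ISe n = 6, MIX n = 7, OSe n = 8). SELENOP lay within -0.18 to 0.06 for OSe minus ISe, while the interval of DIO1 reached from -0.05 to 1.35.

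The remaining genes named in advance were the prolactin receptor PRLR and IGF1, a growth factor made by the liver. They differed between OSe and ISe by -0.57 ± 0.19 (adjusted p = 0.284) and 0.26 ± 0.27 (adjusted p = 0.81). The IGF1 value was 0.40, 0.14 and 0.10 without ISe steers 3, 4 and 5, and 0.17 without OSe steer 6. Across the 3 forms together, LOC619000 had the smallest p-value (limma, adjusted p = 0.0556). Among probe sets with 1 established gene name, LRAT, PDK4, JCAD, DDIT4, TXNIP, KCNK5, TP53INP1, ZC3H12D, PPTC7 and AUTS2 followed, with adjusted p from 0.0556 to 0.0565. The moderated F test of limma called 0 of 26773 probe sets, with 2649 at an unadjusted p under 0.05, and an unmoderated linear model called 0 with 2614. Without MIX steer 1, 2 or 3 it called 16, 12 and 1, without OSe steer 1, 2 or 8 it called 18, 2 and 2, and without ISe steer 1 or 2 it called 17 and 8. With array weights 19 passed.

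Markers of cell types, averaged per steer, passed 0 of 42 exact permutation tests after adjustment, and 5 had an unadjusted p under 0.05. Besides the periportal difference in OSe, periportal markers averaged 10.39 ± 0.21 in MIX against 10.72 ± 0.14 in ISe (exact permutation p = 0.00816, adjusted p = 0.171). Pericentral markers averaged 8.84 ± 0.10 in OSe, 8.97 ± 0.08 in MIX and 8.99 ± 0.10 in ISe (SD). Their exact permutation p was 0.0146 for OSe against MIX and 0.0173 for OSe against ISe (adjusted p = 0.182 for both). Stellate cell and fibroblast markers averaged 7.83 ± 0.08 in MIX and 8.01 ± 0.26 in ISe (exact permutation p = 0.0326, adjusted p = 0.274). Their difference of -0.19 was -0.08 without ISe steer 2, where the exact permutation p was 0.115. It also exceeded 0.05 without MIX steer 2, 3, 5, 6 or 7 or ISe steer 3 or 6 (exact permutation p 0.0541 to 0.0909). Without OSe steer 1 or ISe steer 1, 1 of the 42 tests passed.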

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

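The search for steers that stood apart from their group was planned, and no test in this part was chosen after its result was seen. For each of 156 named genes, each marker list and the first principal component, the gap between the highest or lowest steer and the nearest other steer of its group was divided by the range of the group. In 31 of 513 groups (6.04%) the ratio exceeded the 95% critical value of Dixon's test, which chance exceeds in about 1 of 20 groups, so the number is near what chance gives. No explanation was tested for any of these steers.

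MIX steer 5 stood apart in 5 genes, each time as the lowest of its group: PCDH19 (ratio 0.844), SULT1A1 (0.585), CYP1A1 (0.676), G6PC1 (0.605) and CPT2 (0.629). MIX steer 1 had the highest C3H1orf146 (0.736), the lowest GPX4 (0.678) and the highest averages of the Kupffer cell and macrophage markers (0.634) and of the T and NK lymphocyte markers (0.630). MIX steer 7 had the highest values of the clock genes PER1 (0.5682) and PER2 (0.590) and the lowest BOLA-DQA1 (0.734), and MIX steer 3 had the lowest average of the stellate cell and fibroblast markers (0.569).

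Among ISe steers, steer 2 had the highest average of stellate cell and fibroblast markers (0.728), the highest TIMP1 (0.675) and the lowest AUTS2 (0.763). GPX3 was highest in ISe steer 4 (0.815), SELENOW in ISe steer 6 (0.752) and SCLY in ISe steer 3 (0.766).

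In the OSe group, steer 3 had the lowest CYP1A1 (0.676) and the highest CHAC1 (0.645) and GPX3 (0.580), and steer 6 the lowest RPS9 (0.643), BOLA-DRA (0.582) and BOLA-DMB (0.651). TAT (0.619) and OIT3 (0.554) were highest in OSe steer 1. ECI1 (0.539) and NR1I3 (0.554) were lowest in OSe steer 8, LRAT (0.688) in OSe steer 2 and RPS28 (0.816) in OSe steer 7.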

How the results depend on the processing

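The alternatives with only singly named probe sets and with identical probe sets counted once were not planned, and the others were. Counting identical probe sets once was run only for OSe minus ISe, where it gave 22. Counts of calls were the least stable results. No called gene or list changed its sign under an alternative that tested it. They were chosen on the same arrays that the alternatives refit, so a kept sign was close to given and says little. The cause of each shift in number was not tested, except that fewer probe sets were tested where dim or unnamed ones were left out. The main counts were 0 for the F test, 22 for OSe minus ISe, 1 for MIX minus ISe, 1 for OSe minus MIX and 2 for the midpoint test. The 22 calls kept their sign in each setting that tested them, which were 18 of them with dim probe sets left out and 20 with only singly named probe sets. Of the 24 called results with a gene name, 24 stayed past the threshold with array median centring, array weights, the residual principal component and only singly named probe sets, 22 with a trended and robust variance prior and 15 with quantile normalisation. With dim probe sets left out 19 of the 19 tested stayed, and with only the 2 groups in the fit 2 of 22. Without moderation 24 were lost, with adjusted p from 0.0697 to 0.141. Signal over background was not measured, so no level of detection can be given.

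The F test called 4 probe sets with array median centring, 12 with dim probe sets left out, 11 with the trended and robust prior, 19 with array weights, 5 with the residual principal component, 15 at a threshold of 0.10, 14 with only singly named probe sets, and 0 to 18 with 1 steer left out. OSe minus ISe gave 14 with quantile normalisation, 44 with dim probe sets left out, 0 without moderation, 44 with array weights, 38 with the residual principal component, 57 at 0.10, 1 with only the 2 groups in the fit, 45 with only singly named probe sets, and 0 to 44 with 1 steer left out. MIX minus ISe gave 0 with dim probe sets left out, 0 without moderation, 5 with array weights and 0 to 12 with 1 steer left out. OSe minus MIX gave 0 without moderation, 0 with only the 2 groups and 0 to 1 with 1 steer left out. The midpoint test gave 1 with dim probe sets left out, 0 without moderation and 0 to 4 with 1 steer left out.

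List calls numbered 16, 15 and 5 for OSe minus ISe, MIX minus ISe and OSe minus MIX, against 0, 0 and 0 with estimated correlations and 1, 0 and 0 with fry, the 1 being the periportal list. With 1 steer left out they ranged over 12 to 18, 10 to 18 and 2 to 8. Leaving out dim probe sets ended the calls of the pericentral list for OSe minus ISe (adjusted p = 0.0506) and of MHC class I and II and antigen processing (0.0542), methionine, cysteine and one-carbon metabolism (0.0615), urea cycle (0.0827) and heat shock proteins (0.085) for MIX minus ISe. The MHC call also ended with quantile normalisation (0.0574) and with the mean over probe sets of a gene (0.103), and the call of stellate cells and fibroblasts for OSe minus MIX ended with the residual principal component (0.052). Cell type marker tests past adjustment ranged over 0 to 1 with 1 steer left out. The overlap of calls of OSe and MIX against ISe stayed at 0 with all of its alternatives. MIX minus ISe had 1 call at a threshold of 0.10, 1 with quantile normalisation and 0 with the replicate block. The overlap was thus nearly fixed there and says little about a shared response.

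The groups share replicate numbers, but these did not pair the steers: the deviations of 19 same-numbered pairs correlated at -0.0748 to 0.0379, and 0 of 21 steers were closest to a steer of their own number. With the replicate number as a block the fits called 1 probe set for OSe minus ISe, 0 for MIX minus ISe, 0 for OSe minus MIX, 0 for the midpoint test and 3 for ISe against the mean of the others, 1 of the 24 called results with a gene name stayed past the threshold, and 14, 16 and 3 lists for OSe minus ISe, MIX minus ISe and OSe minus MIX.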

Other observations

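Chosen only after their results were seen were the genes of this and the next paragraph, apart from PRLR, PDK4, ASNS, GLS2, MACIR, NADK2 and G6PC1, the comparison of ISe with the mean of both other groups, and the tests of steers held out, of hepatocyte RNA and of handling or time of day. Hormone signalling genes differed between OSe and ISe in members that passed only when adjusted over the list alone. In the growth hormone, IGF and prolactin list, SOCS2, a feedback inhibitor of growth hormone signalling, was higher by 1.00 ± 0.28 and IGFBP1, an IGF-binding protein of the liver, by 1.08 ± 0.36, while PRLR (-0.57 ± 0.19) and the insulin receptor substrate IRS1 (-0.32 ± 0.10) were lower. The list as a whole was not called (adjusted p = 0.407; adjusted p = 0.672 with an estimated correlation). In ammonia, glutamate and glutamine metabolism ASNS (0.81), PYCR1 (0.61), which makes proline, and GLUD1 (0.22) were higher and GLS2 (-1.25) was lower, again when adjusted over the list alone. Among antioxidant genes the mitochondrial peroxiredoxin PRDX3 (0.52) and thioredoxin TXN (0.32) were higher and the glutathione transferases GSTM2 (-0.60) and GSTM3 (-0.47) lower, and the copper transporter ATP7B was lower by the same adjustment (-0.40 ± 0.10). None of these genes passed over all genes. Camera did not call the lists of ammonia, glutamate and glutamine metabolism, glutathione and NRF2 targets, or peroxide and superoxide defence between OSe and ISe. The list of metallothionein, copper, zinc and iron handling was not called either.

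Steers given selenite alone also differed from the mean of both groups that received SEL-PLEX. Of 26773 probe sets 25 passed in limma, 20 higher and 5 lower in ISe, and 16 of them were also called between OSe and ISe. PDK4 was higher in ISe by 1.51 ± 0.23, a 2.85-fold difference (adjusted p = 0.0191). Genes called here alone included the lysosomal channel TPCN1, higher in ISe by 0.52, PRRG3 (0.78) and ASPA (0.75), and the genes MACIR (-0.56), NADK2 (-0.52) and the phospholipid flippase ATP8B1 (-0.51), lower in ISe. ASPA was dim, at percentile 17.4 of mean signal. The glucose-releasing enzyme G6PC1 (0.60), the NF-kappa B inhibitor NFKBIA (0.61), GADD45A (0.78), SELENBP1 (0.63) and ANXA2 (-1.22) lay just beyond the threshold (adjusted p = 0.0573 for each). The number called was 0 without ISe steer 4, 5 or 6, 7 without ISe steer 3, 10 without MIX steer 3, 12 without MIX steer 5, 13 without OSe steer 5, 14 without MIX steer 4 or OSe steer 2, 15 without MIX steer 6 or OSe steer 4, 38 without ISe steer 2, 58 without MIX steer 1 or 7, 59 without OSe steer 1 and 93 without ISe steer 1. With only singly named probe sets 80 passed. An unmoderated linear model called 0, with 2981 at an unadjusted p under 0.05.

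Of the 100 splits of the steers examined for each count, the real split included, 1 gave as many genes as OSe against ISe. There the real count was 22 and the highest other 1. Chance is thus unlikely by this measure but not excluded, since only some of the possible splits were drawn and several counts were examined. For the midpoint test 2 splits, the real one included, reached the real count of 2 (highest other 2). Random labels thus matched it, and chance is left open. For ISe against the mean of the others 2 splits reached the real 25, but the comparison was chosen after its result was seen, which the splits do not cover, so chance is left open. The highest other gave 93, several times the real count. Whether that reflects a structure of the steers or chance was not examined. The splits say nothing about the F test, since each of the 100 reaches its real count of 0 (highest other 3). Chance could not be excluded for MIX against ISe (7 splits, real 1, highest other 1) or OSe against MIX (8 splits, real 1, highest other 2). Nor could it be for the number of called lists, where 8, 10 and 65 splits reached the real 16, 15 and 5 of OSe minus ISe, MIX minus ISe and OSe minus MIX, with 22, 20 and 19 as the highest others.

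The 19 decreases in OSe against ISe, with a median of -0.82, were weighed against several explanations. The median was still -0.75 with the most influential steer, ISe steer 4, left out, but these genes were chosen on the same steers, so that value excludes nothing, and the number of calls then fell to 0. A single animal is argued against by steers held out in turn. For the 19 strongest decreases chosen without it, 12 of 14 steers lay on the side of their own group, 8 of 8 in OSe and 4 of 6 in ISe. None of 99 other splits of these steers gave more than 11. The difference rested on ISe steers 4, 5 and 6 most, at 0.61, 0.45 and 0.50 above the midpoint of the groups when held out, while ISe steers 1 and 2 lay below it, at -0.11 and -0.06. A smaller share of hepatocyte RNA in OSe, as the only cause of these decreases, is argued against by the hepatocyte identity list. Its median was -0.015 (quartiles -0.077 to 0.019) where the weakest of the decreases was -0.42. A smaller contribution is not excluded, since the decreases were the strongest chosen on these steers. The markers were also bright, averaging 11.97 in OSe and 12.01 in ISe where the highest value was 14.4. Whether such bright signals are compressed was not measured. Time of day or handling before death cannot be told apart from the selenium form, because the immediate early and clock lists were lower in OSe but gave 0.171 as the smaller adjusted p with an estimated correlation, and the times of sampling were not used here. The selenium form itself, the difference the design names, stays open beside it.

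A candidate explanation is a weaker glucocorticoid or fasting response in OSe, since PDK4, DUSP1, DDIT4 and TXNIP are known targets of such signals. A list of 33 other genes of that response was written after the called genes were seen but before its own test, with called genes left out. Its 31 measured members had a median of -0.27 in OSe minus ISe, with 25 below 0. Camera with an estimated correlation gave p = 0.00554, which is not adjusted for the 42 fixed lists tested beside it. Of the measured members, 14 also belong to fixed lists. By the same test 6 of the 42 fixed lists had an unadjusted p under 0.05, and 0 passed after adjustment. The 17 members of the added list in no other list had a median of -0.33 (same test, unadjusted p = 0.0033). For MIX minus ISe camera with an estimated correlation gave an unadjusted p = 0.00972 at a median of -0.24, and for OSe minus MIX p = 0.88 at 0.01. None of the members passed over all genes in limma, and their differences between OSe and ISe went both ways. PER1 (-0.73 ± 0.15), TSC22D3 (-0.41 ± 0.11) and FKBP5 (-0.69 ± 0.26) were below 0, with adjusted p = 0.064, 0.169 and 0.369. For MIX minus ISe FKBP5 was at -0.02, but at -0.19 without ISe steer 2 and 0.10 without MIX steer 4. IGFBP1 (1.08 ± 0.36) and FGF21 (1.12 ± 0.49), which fasting raises, were above 0, with adjusted p = 0.293 and 0.451. The lists of cholesterol synthesis and of fatty acid and triglyceride synthesis, which fasting lowers, were also lower in OSe at the preset correlation. A weaker fasting response would place them higher, so they go against the fasting part of this explanation. The lower values of the added list may reflect intake, handling or the selenium form. They were found and tested on the same animals, and the explanation remains a hypothesis.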
